A study of Rattus norvegicus with 9 samples.

How the data were processed

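Small RNA of the hippocampal CA1 region of adult male Wistar rats was sequenced in 9 libraries, 3 each from a Sham group, a group labelled tGCI26h (transient global cerebral ischemia, with the hour 26 in its label) and a group labelled HPC0h (with the hour 0 in its label). The labels do not expand HPC. Per the labels' protocols, Trizol-extracted total RNA was ligated to adaptors at both ends, copied to cDNA, amplified by PCR, selected for inserts near the length of piRNAs (PIWI-interacting RNAs) and read on an Illumina HiSeq. The submitters' processing notes name cutadapt 1.9.3 and Novoalign 3.02.12 without their roles or settings. No label states the genome build, the catalogue of known piRNAs, the rule that predicted further piRNAs, or how reads that map to several places or entries were counted.

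The deposited values are a score per entry and library: tag counts that the authors normalised to nearly the same total in every library and rounded to whole numbers, per the file headers and the column totals of 961372 to 992081. The table lists 5794 entries with their sequences of 18 to 39 nt. Of these, 512 carry names of the form rno_piR, which are called known piRNAs here, and 5282 carry names of the form novel_N_xN, where the file does not say what either number means. A further 11 lines had been emptied before the table was made available and are not reported here. Blank cells and cells listed at 0 both occur. Blanks were read as 0, and as missing values in an alternative. The raw read number of no library is stated and whole reads could not be recovered from the rounded values, so depth is unknown, no counting interval is given, and a value of 0 means only that an entry is listed at 0 or blank.

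The column headings carry the group but no replicate number. In 7 columns the heading holds 3 numbers, which could stand for 3 animals in a pool, although no label says so. The other 2 columns, 1 in Sham and 1 in tGCI26h, have a heading without numbers. Libraries are named by group and letter: Sham a and b, tGCI26h a and b and HPC0h a, b and c for the 7 numbered columns, and Sham u and tGCI26h u for the 2 unnumbered ones. Because it is not stated whether the libraries are animals, pools or repeats of 1 RNA sample, the p-values measure the spread between these libraries.

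The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), over entries with a mean of at least 1 in all 9 libraries, with the 3 groups in 1 fit and Benjamini-Hochberg adjustment at 0.05. A second count took entries at an unadjusted p below 0.05 and a change of at least 1.5-fold, beside the number that 5% of tests would give. Log2 changes are on the log2(value + 1) scale, which understates changes of entries with low values. Entry groups were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, over the 11 groups with at least 5 tested members. camera compares a group with the other entries, so its direction is relative to them. fry was run beside it. The share of each group in a library total, the Shannon diversity, the share of the 10 most abundant entries and the number of entries above 0 were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Correlations of changes between comparisons that share libraries were set beside 100 simulated draws of unchanged groups.

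The groups were length classes, a first base U, an A at position 10, and ungapped matches with at most 2 mismatches, on either strand, to 5′ ends of tRNAs, Y RNA, 5S and 5.8S rRNA, U1 and U2 snRNA, 7SK RNA, the BC1 RNA and ID element, and B1 and B2 SINE repeats. The group called rRNA thus covers 5S and 5.8S rRNA only, and an entry from any other rRNA was not counted in it. The tests, the groups, the naming rule and most alternatives were fixed before the data were examined. The naming rule takes, for each comparison and direction, the 10 entries with the largest change among those that pass. Where fewer than 5 pass it takes those with the smallest unadjusted p and no overlap between the 3 values of each group, up to 5. It adds the 5 most abundant entries and the most abundant member of each group whose camera test passes. Groups that need a genome (gene features, chromosomes, clusters of loci) were not analysed, since no reference genome was at hand, so no genomic position is given for any entry. Lists of 112 mature microRNAs and of 2 further tRNAs were added after the data had been seen, and sums over all entries matching 1 such sequence were tested as families.

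Alternatives covered the pseudocount, the filter, 3 other scalings of the values, limma without a trend or in its robust form, a fit of only the groups compared, and each library left out in turn. Those added after the data had been seen were the 7 numbered libraries alone (also with a mean of at least 10, or with the 3 other scalings), library type as a covariate, and blanks as missing values. The fit was tested on simulated data in which 200 of 2446 to 2451 entries were changed 2-fold or 4-fold in the comparison of tGCI26h with Sham. The changed entries were drawn only from those at about 10 tags or more in the numbered libraries, so recovery at lower values was not tested. With 9 libraries that vary like the numbered ones the fit recovered 63.5% and 87.5%, and with 7 such libraries 38.0% and 75.0%. When the 2 unnumbered libraries were given their own deviations it recovered 0% at 2-fold among 2773 entries and 0.500% at 4-fold among 2770. With the 7 libraries, wrong calls at 2-fold and 4-fold numbered 8 and 9, beside 76 and 150 recovered entries. They numbered 12 and 20 beside 81 and 170 for HPC0h against Sham, and 21 and 16 beside 88 and 171 for HPC0h against tGCI26h. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 for the figures.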

Results

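The data are normalised tag counts of small RNA from CA1, the hippocampal field whose pyramidal neurons are known for their sensitivity to ischemia, in 3 Sham, 3 tGCI26h and 3 HPC0h libraries. The 9 library totals lay between 961372 and 992081 and show the scaling, not the sequencing depth. Of the 5794 listed entries, 3524 had a value above 0 in some library and 2270 had none. Among the 512 known piRNAs, 95 had a value above 0, and together they held 0.809% ± 0.311 of the Sham, 1.35% ± 0.785 of the tGCI26h and 0.697% ± 0.0622 of the HPC0h totals (SD, n = 3 each). Sham u held 1.17% and tGCI26h u 2.26%, and without them the Sham mean was 0.629%, below HPC0h, and the tGCI26h mean was 0.901%. Part of these shares is a tRNA sequence: rno_piR_005567, a 5′ end of glycine tRNA. It held 1816, 1745 and 4792 tags in Sham a, b and u and 3453, 3153 and 11747 in tGCI26h a, b and u. In HPC0h a, b and c it held 2067, 2452 and 2105. The 7 numbered libraries listed 2558 to 2936 entries above 0, Sham u listed 1201 and tGCI26h u listed 708. Over 2608 entries, the rank correlation between numbered libraries was 0.909 to 0.955 within a group and 0.871 to 0.971 between groups. With the numbered libraries, Sham u reached 0.464 to 0.537 and tGCI26h u reached 0.291 to 0.318.

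The most abundant entries had microRNA sequences. novel_7506_x513 matches miR-9-5p, a microRNA abundant in brain, and held 124000 ± 6838 tags in Sham, 80503 ± 52017 in tGCI26h and 118540 ± 282 in HPC0h (SD, n = 3 each). novel_5323_x834, a form of miR-7-5p, held 43252 ± 27882, 48829 ± 43975 and 62527 ± 7009 in the same order. novel_423_x33476 (miR-99a-5p) held 36851 ± 12639, 55154 ± 14062 and 48304 ± 8110. novel_2237_x2877 (miR-128-3p) held 36811 ± 12991, 34596 ± 11324 and 45439 ± 4521, and novel_8482_x433 (let-7f-5p) held 36336 ± 14765, 36301 ± 31353 and 41349 ± 2933. In the numbered libraries the means were 59030, 73243 and 62527 for novel_5323_x834 and 44821, 54078 and 41349 for novel_8482_x433, so the order of the groups rests on Sham u and tGCI26h u. For novel_423_x33476 they were 44048, 47095 and 48304, so that tGCI26h no longer stood above HPC0h. For novel_7506_x513 the numbered means were 120580, 110540 and 118540, and for novel_2237_x2877 they were 44121, 41133 and 45439, closer together than with all 9 libraries. Across the 1152 entries that match a list of 112 microRNAs added after the data had been seen, the share of the library total was 91.1% ± 1.68 in Sham, 80.1% ± 18.3 in tGCI26h and 91.8% ± 0.942 in HPC0h. The low mean of tGCI26h came from tGCI26h u, at 59.0%, while tGCI26h a and b were at 90.7% and 90.6%.

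**Figure D1:**
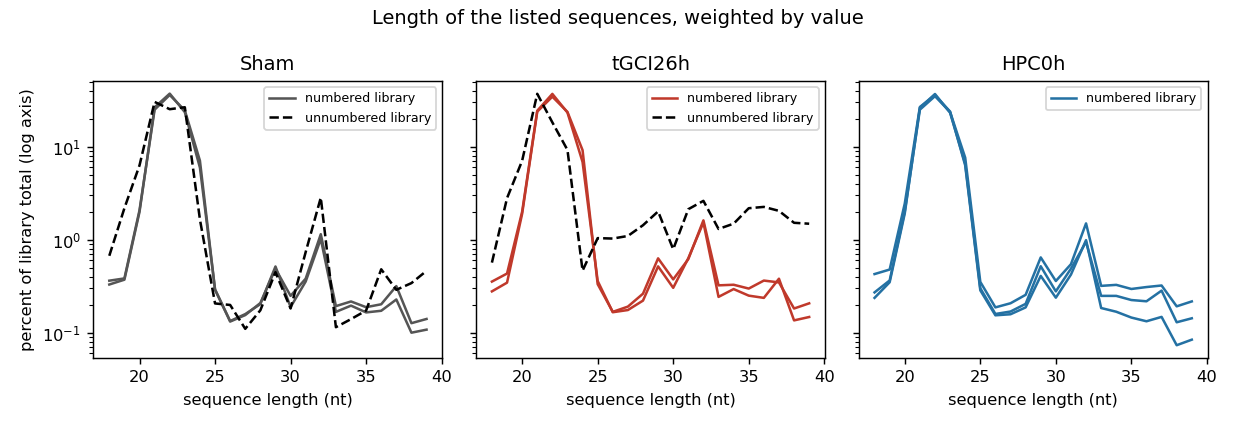
Percent of each library total (log axis) held by sequences of each length in nucleotides, with 1 panel per group and 1 line per library; dashed lines are the 2 unnumbered libraries. Sequences of 18 to 23 nt hold 84.6% to 90.0% of the total in the 7 numbered libraries, and in tGCI26h u, at 75.1%, the longer sequences take a larger share.

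The comparison of tGCI26h with Sham asks which small RNAs of CA1 differ at the labelled 26 h after transient global ischemia. rno_piR_011022 (UAUGGUUUACUGUGUGAACAUAGCCACAAG, 30 nt) held 18 ± 2 tags in Sham and 178 ± 27.8 in tGCI26h (SD, n = 3 each), a log2 difference of 3.23 ± 1.08 (SE). rno_piR_000618 (29 nt), which matches the antisense strand of the B1 SINE, a short repeat of rodent genomes, held 4.00 ± 1.00 and 37.3 ± 8.74, a log2 difference of 2.93 ± 0.99. The other 3 higher entries named by the rule had their highest value in tGCI26h u. novel_9962_x348 held 3.67 ± 4.04 in Sham and 139 ± 206 in tGCI26h, novel_11488_x286 held 15.7 ± 16 and 176 ± 175, and novel_1530_x5063, with the sequence of the 3′ part of an aspartate tRNA, held 0.333 ± 0.577 and 107 ± 180. Without tGCI26h u the tGCI26h means of these 3 were 19.5, 75.5 and 3.

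Lower values in tGCI26h were found for novel_11128_x300 (27 nt, ending in a run of A), at 223 ± 16.5 in Sham and 50.3 ± 44.6 in tGCI26h, a log2 difference of -3.64 ± 1.64 (SE). novel_13804_x223 held 300.3 ± 204 and 54.3 ± 48.7, and novel_13915_x221, which overlaps it in sequence, held 87.0 ± 58.1 and 13.3 ± 11.7. novel_11380_x290 held 15.3 ± 22.2 and 0.667 ± 0.577. The Sham means of the last 3 rest on Sham u, without which they were 182.5, 53.5 and 2.5. All 4 were at 0 or blank in tGCI26h u, and in the numbered libraries the log2 differences were smaller, at -1.61, -1.17, -1.38 and -0.79. novel_3878_x1302, a short form of the miR-15 family, held 1, 1 and 31 tags in Sham a, b and u and was listed at 0 or blank in all tGCI26h and HPC0h libraries.

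None of these passed. In limma, 0 of 2824 entries had an adjusted p below 0.05, 39 had an unadjusted p below 0.05, and 5% of the tests would give 141.2. All 39 also changed by at least 1.5-fold, 31 higher and 8 lower. That count was 14 without Sham u, 214 without tGCI26h a, 242 without tGCI26h b, 100 without tGCI26h u and 20 without any single HPC0h library.

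In the 7 numbered libraries, a selection made after the data had been seen, 13 entries rose and 9 fell at a limma adjusted p below 0.05 among 2608. Of these 22, 14 had identical values within every group, such as 2 tags in both Sham and 1 in both tGCI26h libraries, so that their spread was 0. With a mean of at least 10 tags, 6 rose and 3 fell among 1071. rno_piR_011022 rose from 16 and 18 to 208 and 174 tags (adjusted p = 0.000312), rno_piR_000618 from 3 and 4 to 47 and 30 (adjusted p = 0.0109), and rno_piR_017990 from 12 and 9 to 63 and 64 (adjusted p = 0.00680). rno_piR_000194 and novel_6693_x606, both parts of the initiator methionine tRNA, rose from 3 and 2 to 13 and 12 and from 4 and 3 to 17 and 14. Both held 11 tags in Sham u and 0 or blank in tGCI26h u, the opposite direction. rno_piR_005567, a 5′ end of glycine tRNA, rose from 1816 and 1745 to 3453 and 3153, a log2 change of 0.89 ± 0.13 (SE, adjusted p = 0.0287). novel_11128_x300, novel_10364_x329 and novel_11554_x284, which differ by the number of A at their 3′ end, fell by 1.61, 1.57 and 1.46 on the log2 scale, and with a mean of at least 1 tag they missed the threshold (adjusted p = 0.0694, 0.0698 and 0.0857). At that mean they passed with median-of-ratios (0.0426, 0.0426 and 0.0497) and quantile normalisation (0.0469 each), and missed with TMM (0.0558, 0.0558 and 0.0579). With 3 other scalings and a mean of at least 1 tag, rno_piR_011022 and rno_piR_017990 passed each time. rno_piR_000618 missed with TMM (log2 2.92, adjusted p = 0.0558). rno_piR_000194 and novel_6693_x606 missed with TMM (0.0558 each) and quantile normalisation (0.123 each). rno_piR_005567 missed with median-of-ratios (log2 0.69, adjusted p = 0.121) and TMM (0.67, 0.145).

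**Figure D2:**
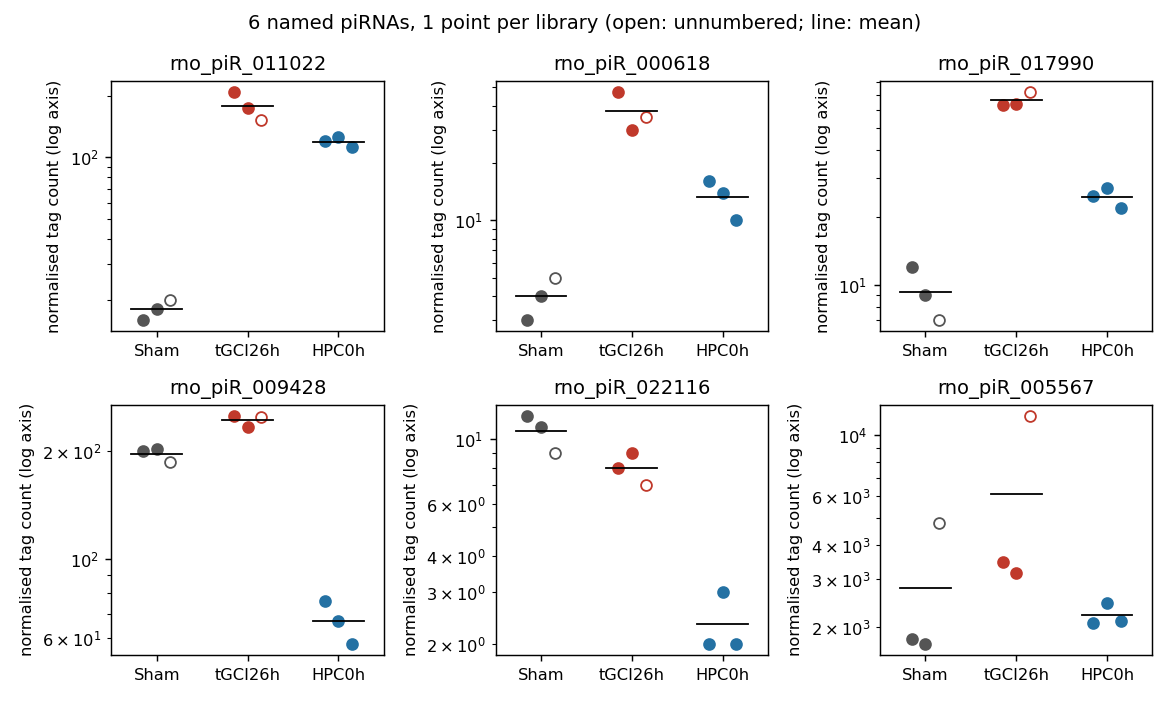
Normalised tag counts (log axis) of 6 known piRNAs, 1 point per library, with open points for Sham u and tGCI26h u and a line at the group mean. rno_piR_011022 lies at 16 to 20 in Sham, 153 to 208 in tGCI26h and 112 to 126 in HPC0h, and rno_piR_009428 lies at 186 to 203, 233 to 250 and 58 to 76.

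By entry group, 8 of 11 groups passed camera at the preset correlation in tGCI26h against Sham. Entries of 18 to 23 nt stood lower than the others, with 898 of 1431 below 0 in log2 (adjusted p = 4.38e-19; adjusted p = 0.255 with an estimated correlation). Entries of 27 to 29 nt stood higher, with 267 of 324 above 0 (3.28e-06; adjusted p = 0.382 with an estimated correlation), as did 258 of 331 of 30 to 32 nt (4.39e-06; 0.382 with an estimated correlation) and 367 of 445 of 33 to 39 nt (5.54e-07; 0.342). Entries of 24 to 26 nt (0.00919; 0.731), rRNA (6.31e-05; 0.255), Y RNA (0.00324; 0.382) and the B2 SINE (0.0442; 0.255) also stood higher, and their calls were lost in the same way. For rRNA and Y RNA the direction turned when tGCI26h u was left out (adjusted p = 0.962 and 0.476). In the 7 numbered libraries both stood lower, and Y RNA passed in that direction (0.267 and 0.000405), but not with an estimated correlation (0.884 and 0.726). That direction is relative to the other entries. As shares of the library total, both were higher in tGCI26h there, at 0.106% against 0.0531% for rRNA and 0.958% against 0.795% for Y RNA. Matches to tRNA 5′ ends missed the threshold at 0.0749, entries that begin with U at 0.110 and entries with A at position 10 at 0.529. In the last 2 groups the median log2 difference was above 0 and the mean below it. Adjusted over the list alone, 0 entries passed in any of the 11 groups.

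The longest classes were led by tRNA and Y RNA sequences. novel_4748_x984 (29 nt), from the 3′ end of Y1 RNA, led the entries of 27 to 29 nt, with 2283 ± 852 tags in Sham and 5335 ± 4057 in tGCI26h (SD, n = 3 each), or 2760 and 3024 in the numbered libraries. novel_3169_x1751 (32 nt), the 5′ end of glycine tRNA, led those of 30 to 32 nt with 7075 ± 4929 and 7084 ± 1896, or 4233 and 5989 in the numbered libraries. novel_10360_x329 (37 nt), the 5′ end of glutamate tRNA, held 1051 ± 827 and 1325 ± 1034. novel_14648_x205, a 3′ part of 5S rRNA, held 929 ± 1269 and 2012 ± 2532, or 196.5 and 564.5 in the numbered libraries. Its values there overlapped, with 237 and 156 in Sham a and b and 217 and 912 in tGCI26h a and b. rno_piR_000999, the most abundant B2 SINE match, held 60 tags in tGCI26h u and was listed at 0 or blank elsewhere. The share of the library total in B1 SINE matches was 0.0204% ± 0.000551 in Sham and 0.0331% ± 0.00840 in tGCI26h (exact permutation p = 0.1, the smallest that 3 against 3 allows).

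**Figure D3:**
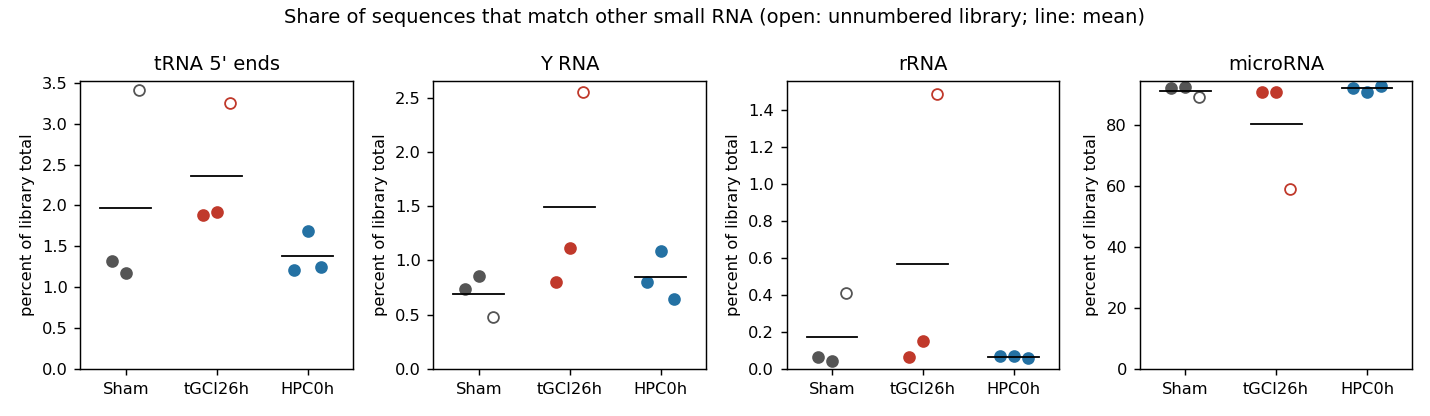
Percent of each library total in entries that match tRNA 5′ ends, Y RNA, rRNA and microRNA, 1 point per library, with open points for Sham u and tGCI26h u and a line at the group mean. Sham u and tGCI26h u hold 3.41% and 3.26% in tRNA 5′ ends, above the 1.17% to 1.92% of the 7 numbered libraries, and tGCI26h u holds the lowest microRNA share at 59.0%.

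The comparison of HPC0h with Sham covers the group whose label carries the hour 0. The 5 higher entries named by the rule, novel_12856_x245, novel_3497_x1505, novel_7652_x500, novel_10161_x339 and novel_2639_x2261, are overlapping pieces of the 5′ part of a glutamine tRNA. novel_2639_x2261 held 0.333 ± 0.577 tags in Sham and 8.00 ± 3.61 in HPC0h (SD, n = 3 each), a log2 difference of 2.74 ± 0.94 (SE). Summed over 46 entries that match a glutamine tRNA, a list added after the data had been seen, the groups overlapped. The sums were 401, 129 and 82 tags in Sham and 442, 621 and 289 in HPC0h, and the share of the library total gave an exact permutation p of 0.2. rno_piR_022116 (UGAAAUAAAACAAAACUGUAAGAAGCCCAG, 30 nt) held 10.7 ± 1.53 in Sham, 8.00 ± 1.00 in tGCI26h and 2.33 ± 0.577 in HPC0h, a log2 difference from Sham of -1.81 ± 0.86. Lower values were also found for novel_5348_x828, another miR-15 form, at 12.3 ± 16.2 and 1.67 ± 0.577, for novel_13013_x241, a form of miR-378-3p, at 6 ± 6.93 and 1 in every HPC0h library, and for novel_13915_x221, at 87.0 ± 58.1 and 17.7 ± 4.73. Without Sham u the Sham means of these 3 were 3, 2 and 53.5.

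None passed here either: limma gave 0 of 2824 entries at an adjusted p below 0.05 and 21 at an unadjusted p below 0.05, 20 higher and 1 lower, against 141.2 for 5% of the tests. The 21 became 46 without Sham a, 154 without tGCI26h u, and 5, 0 and 10 without HPC0h a, b and c. In the 7 numbered libraries 23 entries rose and 13 fell, of which 20 had identical values within every group. With a mean of at least 10 tags 3 rose and 4 fell. rno_piR_011022 rose to 120, 126 and 112 tags from 16 and 18 (log2 2.74 ± 0.18 SE, adjusted p = 0.000782), and rno_piR_000194 and novel_6693_x606, of the initiator methionine tRNA, rose with folds of 4.31 and 3.65. rno_piR_009428 (UACAAAGUGAGUUCCAGGACAGCCAGGGC, 29 nt), a B1 SINE match on the sense strand, fell from 200 and 203 to 76, 67 and 58 (log2 -1.58 ± 0.17 SE, adjusted p = 0.0152). novel_10364_x329, novel_11128_x300 and novel_11554_x284 fell by 1.66, 1.67 and 1.60 on the log2 scale. With a mean of at least 1 tag rno_piR_022116 fell as well (log2 -1.92 ± 0.17 SE, adjusted p = 0.0120).

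Among the entry groups, 5 of 11 passed camera at the preset correlation in HPC0h against Sham. Matches to tRNA 5′ ends stood higher, with 70 of 92 above 0 and a median log2 difference of 1.33 (adjusted p = 1.03e-05; adjusted p = 0.818 with an estimated correlation). Without Sham u the median was 0.55. Their share of the library total was 1.97% ± 1.25 in Sham and 1.38% ± 0.270 in HPC0h (exact permutation p = 0.7), or 1.25% and 1.38% in the numbered libraries. Entries of 24 to 26 nt (0.00355), 27 to 29 nt (0.000113) and 30 to 32 nt (8.42e-05) stood higher, with 224 of 293, 247 of 324 and 246 of 331 above 0, and entries of 18 to 23 nt stood lower relative to the rest (1.53e-09) at a mean log2 difference of 0.03. With an estimated correlation each of these had an adjusted p = 0.818. Entries of 33 to 39 nt (0.0757), first base U (0.971), A at position 10 (0.688), B2 SINE (0.688), rRNA (0.971) and Y RNA (0.851) missed the threshold, and adjusted over the list alone 0 entries passed in any group. The share in B1 SINE matches was 0.00812% ± 0.00121 in HPC0h (exact permutation p = 0.1 against Sham), and the share in ID element matches was 0.00238% ± 0.000944 in Sham and 0.00471% ± 0.000810 in HPC0h (exact permutation p = 0.1). snRNA matches held 0.00175% ± 0.00157 in Sham and 0.00344% ± 0.000974 in HPC0h (exact permutation p = 0.2), or 0.00262% and 0.00344% in the numbered libraries, and no entry matched 7SK RNA.

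The comparison of HPC0h with tGCI26h shows the difference between the treated groups directly. All 5 lower entries named by the rule, novel_1530_x5063, novel_5380_x822, novel_6529_x628, novel_8504_x431 and novel_9954_x349, are overlapping pieces of the 3′ part of an aspartate tRNA. novel_1530_x5063 held 3 tags in tGCI26h a and b, 314 in tGCI26h u and was listed at 0 or blank in HPC0h. The other 4 shared the same values, 2, 2 and 145 in tGCI26h and 0 or blank in HPC0h. The higher entries, novel_10159_x339, novel_8560_x427, novel_8901_x405 and novel_8954_x402, are pieces of 1 sequence with 3 tags in each HPC0h library and 0.333 ± 0.577 in tGCI26h (SD, n = 3), and novel_6687_x607, which contains them, held 7 tags in each HPC0h library and 1.67 ± 1.53 in tGCI26h.

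In limma 0 of 2824 entries passed, and 8 had an unadjusted p below 0.05, all lower in HPC0h by at least 1.5-fold. The 8 became 172 without tGCI26h a, 181 without tGCI26h b, and 5 without tGCI26h u, Sham b, HPC0h a or HPC0h b. In the 7 numbered libraries 9 entries rose and 3 fell, of which 11 had identical values within every group. The remaining 1 was rno_piR_009428, which fell from 250 and 233 tags in tGCI26h to 76, 67 and 58 (log2 -1.84 ± 0.13 SE, adjusted p = 0.00719). With the median-of-ratios and TMM scalings it missed the threshold (log2 -1.88 and -1.85, adjusted p = 0.0918 and 0.0787). With quantile normalisation it passed (log2 -1.80, 0.0176), as it did with a mean of at least 10 tags (0.0106).

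For the entry groups, 5 of 11 passed camera at the preset correlation in HPC0h against tGCI26h. Entries of 18 to 23 nt stood higher (adjusted p = 0.00254; adjusted p = 0.923 with an estimated correlation), with 1085 of 1431 above 0, and tRNA 5′ ends stood higher (0.0122; 0.933), with 78 of 92 above 0. The call for tRNA 5′ ends was lost without tGCI26h u (0.577), and in the 7 numbered libraries the direction turned (0.890). Their share of the library total was lower in HPC0h, at 1.38% ± 0.270 against 2.36% ± 0.783 in tGCI26h (exact permutation p = 0.1). Entries of 33 to 39 nt stood lower relative to the rest (0.000417; 0.671), although 280 of 445 were above 0 and their median log2 difference was 0.80 and their mean -0.03. rRNA (1.62e-05; 0.279) and Y RNA (0.000379; 0.465) stood lower. When tGCI26h u was left out rRNA and Y RNA turned to higher (adjusted p = 0.180 and 0.117), and 3 groups passed; 3 also passed without HPC0h c. With the 7 numbered libraries both stood higher, and rRNA passed in that direction (0.0104 and 0.0808), but not with an estimated correlation (0.923 for both). As shares of the library total, both were lower in HPC0h there, at 0.0668% against 0.106% for rRNA and 0.846% against 0.958% for Y RNA. The groups of 24 to 26 nt (0.983), 27 to 29 nt (0.229), 30 to 32 nt (0.309), first base U (0.103), A at position 10 (0.983) and B2 SINE (0.134) missed the threshold, and adjusted over the list alone 0 entries passed. The share in B1 SINE matches, 0.00812% ± 0.00121 in HPC0h and 0.0331% ± 0.00840 in tGCI26h, gave an exact permutation p = 0.1.

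Whether values that differ in tGCI26h lie back near Sham in HPC0h was examined across 2824 entries, which are not independent replicates. As the labels of these groups also differ in the hour, nearness to Sham could not be assigned to treatment or to time. The log2 differences of tGCI26h from Sham and of HPC0h from tGCI26h had a Pearson r of -0.67, where unchanged groups sharing the same libraries gave -0.50 on average (-0.54 to -0.46 in 100 draws). The covariance was -1.24 against a simulated -0.870. The differences of tGCI26h and of HPC0h from Sham had r = 0.44, where chance gave 0.50 (0.46 to 0.55), and a covariance of 0.672 against 0.870. In the 7 numbered libraries these values were -0.30 against a simulated -0.55, and 0.77 against 0.55, with covariances of -0.0602 against -0.0888 and 0.238 against 0.0888. Both r thus lie on the other side of the simulated value than with 9 libraries. The simulation takes no account of library type, which leaves the departures with 9 libraries unread. With the numbered ones alone, both r lay outside the simulated ranges, -0.60 to -0.50 and 0.47 to 0.61. The draws vary each entry on its own, while many entries overlap or share all their values. The simulated ranges are therefore too narrow, and no departure is read from them. The first r was -0.92 without Sham u (simulated -0.45) and -0.30 without tGCI26h u (simulated -0.60). The second was 0.27 without Sham u (simulated 0.60), 0.95 without tGCI26h u (0.45), and 0.19 without either tGCI26h a (0.45) or b (0.44). No group could be split into parts of at least 2 libraries, so the part of each r that comes from the shared libraries was not removed.

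Diversity and detection were compared by exact permutation, which with 3 against 3 gives no p below 0.1. The Shannon diversity was 6.23 ± 0.256 bits in Sham, 6.46 ± 0.510 in tGCI26h and 6.16 ± 0.0422 in HPC0h (SD, n = 3 each), with exact permutation p of 0.5 for tGCI26h and 1.0 for HPC0h against Sham and 0.4 between them. The 10 most abundant entries held 47.5% ± 3.79, 45.8% ± 6.51 and 48.5% ± 0.476 of the total, with exact permutation p of 0.7, 1.0 and 1.0, or 49.7%, 49.5% and 48.5% in the numbered libraries, where HPC0h is the lowest. The number of entries above 0 was 2185 ± 860, 2147 ± 1248 and 2884 ± 49.0, with exact permutation p of 1.0, 0.1 and 0.5. Each HPC0h library listed more entries above 0 than any Sham library. In the numbered libraries alone (n = 2, 2 and 3), the diversity was 6.08 ± 0.00636, 6.17 ± 0.00636 and 6.16 ± 0.0422 bits, and the number of entries above 0 was 2677 ± 168, 2867 ± 97.6 and 2884 ± 49.0 (SD).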

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

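All tests of explanations in this part except 1, the share of other entries at a like level that match between library types, were chosen after the result they bear on was seen. The numbers inside the entry names were not used in any comparison above. The largest of them, 7501380, belongs to novel_2_x7501380 (UGGAAGACUAGUGAUUUUGU, a short form of miR-7-5p), whose values were 32 and 25 in Sham a and b, 33 and 41 in tGCI26h a and b, and 32, 38 and 46 in HPC0h. What the number counts is not stated in the files.

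Sham u and tGCI26h u stood apart from the 7 numbered libraries, with rank correlations of at most 0.537 and 0.318 with them. A lower depth alone was argued against: numbered libraries thinned until they listed as few entries still reached at least 0.732 and 0.606, and the smaller gap was 0.195. Blood alone, which would bring miR-451 of red blood cells but no neuronal RNA, was argued against by miR-124, a microRNA of neurons. It was 13.2 and 27.1 times as high as in the numbered libraries of the group, beside 13.0 and 34.6 for miR-451. miR-128 (0.555 and 0.589), miR-127 (0.353 and 0.251) and miR-7 (0.239 and 0) were lower. Dilution by blood alone would lower RNA that blood lacks by a like factor and would not raise miR-124. The unlike ratios therefore argue against it for these microRNAs, while blood together with another cause was not excluded. A preparation or counting shared by the 2 libraries stays open: across 1071 entries their deviations from their own groups correlated at r = 0.332, above the 0.0173 to 0.147 of thinned pairs, so they may have been made or processed apart from the rest. No biological explanation was tested, since the labels give no difference between the libraries of a group.

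A few known piRNAs did not share that difference. rno_piR_000553, rno_piR_000618, rno_piR_009428, rno_piR_011022, rno_piR_014971, rno_piR_017990 and rno_piR_022116, 7 of the 16 known piRNAs listed in both unnumbered libraries, lay within 1.5-fold of the numbered mean of their group in both, as did 9 of 404 other entries. That any entry at such levels would match was argued against, since 1 of 208 others in the same range did (0.481%). That their values were counted like the rest of the column was argued against for rno_piR_000553, rno_piR_000618, rno_piR_017990 and rno_piR_022116. Of these values, 6 lie below the smallest value of the entries not named rno_piR, which is 10 in Sham u and 34 in tGCI26h u. rno_piR_009428, rno_piR_011022 and rno_piR_014971 have no value below it. Low values also occurred without a match, in rno_piR_022845 and rno_piR_025697, making 10 such values in 6 known piRNAs. They therefore do not account for the match. How the 7 came to match was not shown. They include rno_piR_011022, rno_piR_000618, rno_piR_022116, rno_piR_009428 and rno_piR_017990, so the points of the 2 unnumbered libraries add no independent weight to the differences of these piRNAs. That limit extends to the share in B1 SINE matches, most of whose tags are rno_piR_009428.

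The number in a name did not follow the value of its entry: across 5282 entries the rank correlation of the number with the mean value was 0.0504, which argues against both being counts of the same reads. In 403 sets of entries with the same first 18 bases, the highest value was on a longer entry than the highest number in 384, on an entry of the same length in 19 and on a shorter one in 0, or 100% longer among those that differ. A shorter peak was impossible in 157 sets, where the highest number was on the shortest entry. In the 227 sets with both shorter and longer entries, 227 had the longer peak, where 99.6 would if it fell on any member alike. Reads of a short sequence may be counted under a longer entry, which stays open, and no biological explanation was tested.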

How the results depend on the processing

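The tests of other splits of the libraries were written down after the counts they bear on had been seen. The alternatives named below as added were also chosen after the data had been seen, because of the 2 unnumbered libraries. In triplets of values the order is tGCI26h against Sham, HPC0h against Sham, and HPC0h against tGCI26h. No paired analysis was possible because the columns carry no replicate numbers. Count models were not run, since whole reads could not be recovered from the values. The 2 unnumbered libraries limit what all 9 can show: with their deviations, simulated 4-fold changes were recovered in 1, 0 and 0 of 200 entries, against 175, 176 and 177 with 9 libraries like the numbered ones. The 30 named comparisons of entries kept their direction and their side of the threshold in all 546 values under the alternatives set beforehand, and in 141 of 164 under the added ones, where 23 came to pass in the same direction. The naming rule, which asks for no overlap between groups, largely fixed the direction, and the low recovery largely fixed the side. These counts are therefore no test of robustness. The comparisons of 18 groups kept both in 246 of 286 values under the alternatives set beforehand and in 10 of 36 under the added ones. There 36 and 16 no longer passed, and 4 and 10 changed sign. The cause was not tested except where stated.

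Counts of entries passing in limma were 0, 0 and 0 with all 9 libraries, with 39, 21 and 8 at an unadjusted p below 0.05 and at least 1.5-fold. They stayed 0 with the other pseudocounts, filters, scalings and forms of limma, and without each library in turn. A fit of only the 2 groups compared gave 0 (limma, 4 at an unadjusted p below 0.05), 8 and 2. Among the added alternatives, the 7 numbered libraries gave 22 (13 higher and 9 lower), 36 (23 and 13) and 12 (9 and 3). With a mean value of at least 10 they gave 9, 7 and 1. With median-of-ratios scaling they gave 9 (6 higher and 3 lower), 22 (12 and 10) and 0 (118 at an unadjusted p below 0.05), with TMM scaling 3 (3 and 0), 24 (14 and 10) and 0 (124 unadjusted), and with quantile normalization 7 (4 and 3), 17 (4 and 13) and 2 (0 and 2). Under these 3 scalings 222 of 222 values of the entries and families that passed had the same direction, and 70 also passed. The calls were picked in the same 7 libraries, so rescaling could hardly turn their direction. The count of kept directions is therefore no test of robustness. Of the 22, 36 and 12 entry calls, 14, 20 and 11 had identical values within every group. Blank cells as missing gave 3, 3 and 1. Library type as a covariate gave 0, 0 and 0 in limma, with 116, 136 and 41 at an unadjusted p below 0.05.

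Counts at an unadjusted p below 0.05 and at least 1.5-fold were 39 (31 higher and 8 lower), 21 (20 and 1) and 8 (0 and 8). A pseudocount of 5 gave 20 in the first and 5 in the third comparison, and no filter gave 75 in the second and 38 in the third. A mean value of at least 10, under which fewer entries are tested, gave 17, 3 and 1. TMM scaling gave 30 (23 and 7), 35 (31 and 4) and 12 (4 and 8), and quantile normalization gave 80 (26 and 54), 69 (47 and 22) and 16 (7 and 9). Only the 2 groups compared gave 4, 141 and 33. The 7 numbered libraries gave 265 (221 and 44), 278 (239 and 39) and 60 (36 and 24), and with a mean value of at least 10 they gave 124, 112 and 25. With median-of-ratios scaling they gave 235 (166 and 69), 224 (154 and 70) and 79 (32 and 47), with TMM scaling 239 (165 and 74), 231 (161 and 70) and 75 (38 and 37), and with quantile normalization 203 (114 and 89), 216 (137 and 79) and 91 (56 and 35). Library type as a covariate gave 114, 133 and 37, and blank cells as missing 193, 198 and 31. Without 1 library the ranges were 14 (without Sham u) to 242 (without tGCI26h b), 0 (without HPC0h b) to 154 (without tGCI26h u), and 5 to 181 (without tGCI26h b). The first was also 214 without tGCI26h a, 100 without tGCI26h u and 20 without any 1 HPC0h library. The second was 46 without Sham a, 5 without HPC0h a and 10 without HPC0h c, and the third was 172 without tGCI26h a.

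Of the 11 groups, 8, 5 and 5 passed camera at the preset correlation and 0, 0 and 0 at an estimated correlation, also in the 7 numbered libraries. With a mean value of at least 10 the third count was 8. Without 1 library the ranges were 6 to 9, 4 to 6 and 3 to 5, with 3 without tGCI26h u or HPC0h c. Signs changed in the 7 numbered libraries, in the same 7 with an estimated correlation, and without tGCI26h u. In that order the adjusted p for tGCI26h against Sham was 0.267, 0.884 and 0.962 for rRNA (3.30e-07 to 0.962 over its alternatives) and 0.000405, 0.726 and 0.476 for Y RNA (0.000187 to 0.726, without 1 library 0.000194 to 0.476). For HPC0h against tGCI26h it was 0.0104, 0.923 and 0.180 for rRNA (4.42e-08 to 0.923, without 1 library 6.87e-07 to 0.180) and 0.0808, 0.923 and 0.117 for Y RNA (1.94e-05 to 0.923, without 1 library 9.77e-05 to 0.117). The sign for tRNA 5′ ends changed in the first 2 of these, with 0.890 and 0.923 (0.00601 to 0.933). As leaving out tGCI26h u was enough to change the sign for rRNA and Y RNA, those directions depend on that library.

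The r of the differences of tGCI26h from Sham and of HPC0h from tGCI26h, -0.67 in the report, and the r of the 2 differences from Sham, 0.44, were -0.72 and 0.37 with a pseudocount of 5, and -0.77 and 0.31 with a mean value of at least 10. TMM scaling gave -0.56 and 0.50, median-of-ratios scaling -0.59 and 0.48, and quantile normalization -0.63 and 0.36. Unchanged groups gave -0.50 and 0.50 on average under each of these scalings. The covariance of the first pair was smaller in size than simulated with TMM (-0.832 against -1.045) and median-of-ratios scaling (-0.748 against -0.820). The 7 numbered libraries gave -0.30 and 0.77, and with a mean value of at least 10 -0.39 and 0.76. Without 1 library they ranged from -0.92 (without Sham u) to -0.30 (without tGCI26h u) and from 0.19 (without tGCI26h b) to 0.95 (without tGCI26h u). The median log2 difference over the entries was 0.14, 0.53 and 0.72, with TMM scaling -0.05, 0.73 and 1.07, and with quantile normalization 0.06, 0.05 and 0.07. In the 7 numbered libraries it was 0.21, 0.21 and 0.00. Differences in diversity, in the share of the 10 most abundant entries and in entries detected moved by less than 1 SD of all 9 libraries in each alternative, an SD widened by the unnumbered ones. With the 7 numbered libraries the Shannon diversity in bits, HPC0h minus Sham, turned from -0.072 to 0.0755. The share of the 10 most abundant piRNAs in percent, HPC0h minus Sham, turned from 1.07 to -1.12, and HPC0h minus tGCI26h from 2.76 to -0.99. For the number of piRNAs detected, tGCI26h minus Sham turned from -37.3 to 190.5, and HPC0h minus tGCI26h went from 737 to 17.3.

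The 6 libraries of 2 groups can be split in 10 ways, too few for a share under 0.05. Counts of passing entries were 0 in each comparison, with 0 as the highest of the other splits, so 10 of 10 splits gave as many. Counts at an unadjusted p below 0.05 and 1.5-fold were 39 (highest other 1042), 21 (11) and 8 (24), reached by 5, 1 and 5 splits, and groups passing were 8 (8), 5 (6) and 5 (7), reached by 4, 5 and 3 splits. The split with 1042 sets Sham a, tGCI26h a and tGCI26h b against the other 3, which include both unnumbered libraries, and points to a structure of the samples that follows library type.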

Other observations

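The families and the tests in this part were chosen after the data had been seen. Sums over all entries of 1 small RNA gave 103 families with a mean of at least 10 tags in the 7 numbered libraries. Entries of a family can overlap, so a sum may count the same tags more than once. For example, the sequence of rno_piR_005552 lies within that of rno_piR_000194, and both held 3 and 2 tags in Sham a and b. The initiator methionine tRNA rose from 11 and 9 tags in Sham a and b to 44 and 38 in tGCI26h a and b, a fold of 3.82 (limma adjusted p = 0.000441), and to 39, 44 and 46 in HPC0h, a fold of 4.01 (adjusted p = 0.000169). B1 SINE matches fell in HPC0h, to 92, 81 and 68 tags from 203 and 208 in Sham (fold 0.391, adjusted p = 0.00191) and from 298 and 263 in tGCI26h (fold 0.287, adjusted p = 0.000464). Most of those tags are rno_piR_009428. Both families passed with 3 other scalings of the same 7 libraries. They also kept their direction, which such rescaling could hardly turn. With all 9 libraries the initiator methionine tRNA turned to lower in tGCI26h than in Sham (fold 0.755), because Sham u held 33 tags and tGCI26h u held 0. In that fit 0 of 114 families passed in limma in any comparison, and 2, 1 and 1 had an unadjusted p below 0.05 in tGCI26h against Sham, HPC0h against Sham and HPC0h against tGCI26h.

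Other families missed the threshold in the 7 numbered libraries at the deposited scaling. 5′ ends of histidine tRNA held 733 and 476 tags in Sham, 935 and 2143 in tGCI26h and 1773, 1757 and 1635 in HPC0h, a fold of 2.91 in HPC0h over Sham (adjusted p = 0.0520). With TMM scaling this family passed (log2 1.31, adjusted p = 0.0475), and with median-of-ratios and quantile scaling it missed (0.0812 and 0.0652). miR-210-3p, known for its induction by hypoxia, held 21 and 26 in Sham, 18 and 32 in tGCI26h and 41, 43 and 39 in HPC0h (fold 1.72 over Sham, adjusted p = 0.199). miR-132-3p, a microRNA induced by neuronal activity, held 827 and 755, 637 and 774, and 1014, 1044 and 905 (log2 0.49 in HPC0h over tGCI26h, adjusted p = 0.171). miR-21-5p held 3108 and 3100, 2392 and 2251, and 3009, 2692 and 3255 (fold 0.748 in tGCI26h over Sham, adjusted p = 0.349).

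rno_piR_009428 and rno_piR_000618 match opposite strands of the same stretch of the B1 SINE. The first held 200, 203 and 186 tags in Sham, 250, 233 and 248 in tGCI26h and 76, 67 and 58 in HPC0h. The second held 3, 4 and 5 in Sham, 47, 30 and 35 in tGCI26h and 16, 14 and 10 in HPC0h, where it did not pass against Sham in the 7 numbered libraries (limma adjusted p = 0.117). For both, the last value in Sham and in tGCI26h is from the unnumbered library and adds no independent weight.

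Among entries of 27 to 32 nt that begin with U and match no listed microRNA, tRNA, rRNA or Y RNA, the lengths and first base typical of piRNAs, 293 of 590 had a value above 0. They held 0.326% ± 0.0274 of the total in Sham, 0.771% ± 0.591 in tGCI26h and 0.389% ± 0.0767 in HPC0h (SD, n = 3 each). The tGCI26h mean rests on tGCI26h u, at 1.45%, and was 0.430% without it. These shares gave exact permutation p of 0.1, 0.3 and 0.3 for tGCI26h and HPC0h against Sham and for HPC0h against tGCI26h.

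Of the 5794 entries, 3646 (62.9%) are contained in a longer entry. Of the 3524 entries with a value above 0 in some library, 1458 share all 9 values with another entry, in 365 sets. Counts of entries therefore exceed the number of separate molecules.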
